A study of Homo sapiens with 2 samples.

How the data were processed

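RNA was measured in 2 cultures of OCI-AML3, 1 exposed for 24 h to 50 nM omipalisib and 1 to DMSO. Per the labels' protocols, cells grew in MEM alpha medium with serum, total RNA was isolated on NucleoSpin columns, and strand-specific libraries were built with Illumina's TruSeq stranded chemistry. Each library has 1 file of raw counts per gene, which the authors deposited without normalization. Per the file headers, the counts were made with featureCounts 2.0.1 over exons grouped by gene, for read pairs with both ends aligned, with a check of the fragment length and with the reverse-strand setting (2). Strand-specific counting keeps antisense neighbours apart, but genes that overlap on the same strand lose the fragments they share. The header records no option for fragments with several alignments, and the tool leaves these out by default, so genes with near-identical copies are undercounted and are named as uncertain. Of the named genes, ASNS, CDKN1B, MCL1, CD44, HERPUD1, RPL3, RPL12 and SNHG12 overlap an annotated gene on their strand, besides those where the overlap is stated. The aligner, and whether RNA was selected by poly(A) tail or by removal of ribosomal RNA, are not given in the sources used here.

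The submitters' processing notes name the builds hg19 and GRCh37. The coordinates in the files are those of GRCh38: both files list the same 60623 Ensembl genes at the same positions, 58516 of these are in GENCODE release 29, and 58468 of those overlap that release's position on GRCh38. Coordinates are therefore given as GRCh38. Symbols and biotypes came from the same release and the gene name table supplied with it, with 58584 genes given a symbol. Genes that the release does not hold have no biotype here.

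The unit of the deposited values is counts, and whole numbers summed to 26367832 in DMSO and 22599164 in omipalisib. A gene at 3 counts has 0.116 CPM in DMSO and 0.131 CPM in omipalisib. Libraries were scaled with the TMM factors of edgeR 4.0.16 in R 4.3.3, which were 0.983 for DMSO and 1.02 for omipalisib. The log2 ratio was taken after 0.5 was added to each count. Its 95% interval is the exact Clopper-Pearson interval of the omipalisib share of the summed count, turned into a ratio, and covers counting error only. Reads without molecular identifiers are not independent molecules, and biological variation between cultures is outside these intervals. The labels give 1 library per group, so no model was fitted and no p-value was computed. In place of a test, a gene was counted as at least 2-fold higher or lower by a rule of size: a summed count of at least 20, a ratio of at least 2 either way, and an interval that excluded a ratio of 1.

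A set of 41 gene lists was fixed to fit the line and the drug. For each, the median log2 ratio of members with a summed count of at least 20 was set against the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression, and its percentile is given. A list is described as standing apart at or below percentile 2.5 or at or above 97.5. The interval of a median comes from order statistics, and lists of under 6 measured genes show the range instead. The lists hold 915 measured genes, of which 21 are in more than 1 list; for example, 4 glycolysis genes are also HIF targets. Lists of erythroid and megakaryocyte, lymphoid, and stromal and epithelial markers stood for cells other than the line, and 3, 5 and 8 of these markers reached 1 CPM in DMSO.

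Single genes were named by 3 parts of a rule. The first took the 12 higher and the 12 lower protein-coding genes, with at least 100 counts in 1 library and not mitochondrially encoded, whose intervals lay farthest from 0. The next took up to 3 members of each list in the direction of its median and 1 in the other direction. The last took the drug target genes and a fixed set of metabolic, cell cycle, myeloid and survival genes, whatever their values, and 1 gene of that set is not reported here. SPRY4, DUSP6, EPOR, VIM and SREBF2 are outside the rule and were named after their values were seen. The grouping, lists, rules and all alternatives except the removal of a trend with gene length were chosen before the data were examined.

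The procedure was tested on simulated counts, drawn for the real genes at the real depths with 200 genes changed, of which the size step ran on 15725 genes. For this comparison it recovered 90.0% of genes simulated higher and 84.0% of those simulated lower by a log2 ratio of 1.2, and 100% and 88.0% at 2.0. It counted 64 of 15532 unchanged genes, and the interval covered the true ratio for 95.5% of them. Of 200 unchanged lists of 20 randomly drawn genes, 5.0% lay outside the 2.5 and 97.5 percentiles, a share that the design sets in advance. Counts were drawn for each gene independently with Poisson error. Variation between cultures and between genes that vary together was not simulated, so these rates cover counting error only.

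The alternatives were scaling by total counts, by the median-of-ratios size factors of DESeq2 1.42.0, by the upper quartile, and by totals without mitochondrial genes and the 50 most abundant genes; 5 added to each count; the DMSO library thinned to the other's total; no minimum count or 200; ratios of 1.5 and 4; an interval wholly past a ratio of 2; protein-coding genes alone; and random lists unmatched or matched on length too. Replicates could not be left out in turn, since each group has 1. Relative to TMM the scalings shifted all log2 ratios by −0.04 to 0.06. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.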

Results

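The series profiled gene expression in OCI-AML3, a human acute myeloid leukaemia line of myelomonocytic type that carries mutant NPM1, after 24 h in 50 nM omipalisib or in its vehicle, DMSO. Omipalisib (GSK2126458) is a small molecule that inhibits the class I phosphoinositide 3-kinases (PI3K) and mTOR, the kinase that couples growth factor and amino acid supply to protein synthesis. Strand-specific RNA sequencing libraries were made from total RNA, and fragments were counted per gene. There was 1 library per treatment. The DMSO library held 26367832 counted fragments and the omipalisib library 22599164, and 15660 genes with a summed count of at least 20 were measured, 12260 of them protein-coding. All log2 ratios are omipalisib over DMSO. They are relative to the rest of each library after scaling and do not give amounts per cell. With 1 library on each side the differences have no replicate check, so no p-value is given, and each 95% interval covers counting error only and compares these 2 libraries, not the conditions. A gene is counted as higher or lower where that interval excluded 0.

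The comparison asks how the transcriptome of the line differed after a day of PI3K and mTOR inhibition. In the omipalisib library, G1/S and G2/M genes, ATF4 targets, tRNA synthetases and genes of serine and one-carbon metabolism, of cholesterol and nucleotide synthesis, of the mitochondrial ribosome and respiratory chain, of endoplasmic reticulum and heat stress and of the interferon response were lower as groups. FOXO targets, immediate early and feedback genes of the MAPK pathway, ribosomal protein genes and a set of monocyte genes were higher as groups. All 38 measured G1/S genes were lower, with a median log2 ratio of −0.70. Of the 32 measured FOXO targets, 24 were higher, with a median of 0.40. The genes with the largest differences were CD86, a costimulatory receptor of antigen-presenting cells, with a log2 ratio of 2.85 (2.54 to 3.18), and S100A8, a calcium-binding protein of neutrophils and monocytes, with −1.82 (−2.18 to −1.50), by the rule for single genes that was fixed in advance.

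Of the 15660 genes, 4084 were higher, 4486 were lower, and for 7090 the interval included 0. A ratio of at least 2 was reached by 629 higher genes (4.02% of those measured) and 202 lower genes (1.29%). The higher set held 366 protein-coding and 193 long noncoding RNA genes, the lower set 124 and 19. Most of these genes had few counts: the median summed count was 77 in the higher set and 52.5 in the lower set, against 967 over all measured genes. Among genes with a summed count of at least 200, 193 were at least 2-fold higher and 37 at least 2-fold lower. Long noncoding RNA genes took 1.36% of the fragments in the DMSO library and 1.84% in the omipalisib library. Mitochondrially encoded genes took 5.73% and 5.93%. Across the measured genes, which are not independent replicates, Pearson's r of log2(CPM + 1) between the libraries was 0.989.

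Among protein-coding genes with at least 100 counts in a library, the higher genes with the largest counting bounds included several of myeloid cells. CD86 (chromosome 3, 122055362 to 122121139, GRCh38) had 94 counts in DMSO and 602 in omipalisib. CD14, the monocyte lipopolysaccharide coreceptor, had 53 and 221 counts, a log2 ratio of 2.22 (1.80 to 2.70), and ADGRE1, the human F4/80 gene, had 2.08 (1.67 to 2.53). CDKN2B, which encodes the CDK4 and CDK6 inhibitor p15, had 150 and 742 counts, a log2 ratio of 2.48 (2.23 to 2.74). ABCA9 and ABCA6, neighbouring lipid transporter genes on chromosome 17, had log2 ratios of 2.62 (2.40 to 2.86) and 1.79 (1.62 to 1.96). The others were the metalloprotease-like ADAM28 (2.66), the acyl-CoA synthetase ACSM3 (2.53), the neuropeptide Y receptor NPY1R (2.51), the neurotrophin receptor NTRK3 (2.33) and the transcription factor AFF3 (2.16). AMY2B had a log2 ratio of 2.34, but it overlaps RNPC3 on the same strand and resembles the other amylase genes, so its counts are uncertain. ACSM3 also overlaps an annotated gene on its strand.

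Among the lower genes, S100A8 had 365 and 91 counts. PSAT1 (chromosome 9), an enzyme of serine synthesis, had 2032 and 681 counts, a log2 ratio of −1.40 (−1.53 to −1.28). DDIT4, a stress-induced inhibitor of mTORC1, had 797 and 238 counts, a log2 ratio of −1.57 (−1.79 to −1.36). TFRC, the transferrin receptor, had 8300 and 3115 counts, a log2 ratio of −1.24 (−1.30 to −1.18). ERH, a small nuclear protein, had −1.19 (−1.27 to −1.12). The others were the proteoglycan CSPG4 (−1.69), the cadherin CDH6 (−1.68), the ganglioside synthase B4GALNT1 (−1.62), CTXN1 (−1.62), the Toll-like receptor homologue CD180 (−1.61), the secreted glycoprotein STC2 (−1.59) and the glutathione-degrading enzyme CHAC2 (−1.43).

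**Figure D1:**
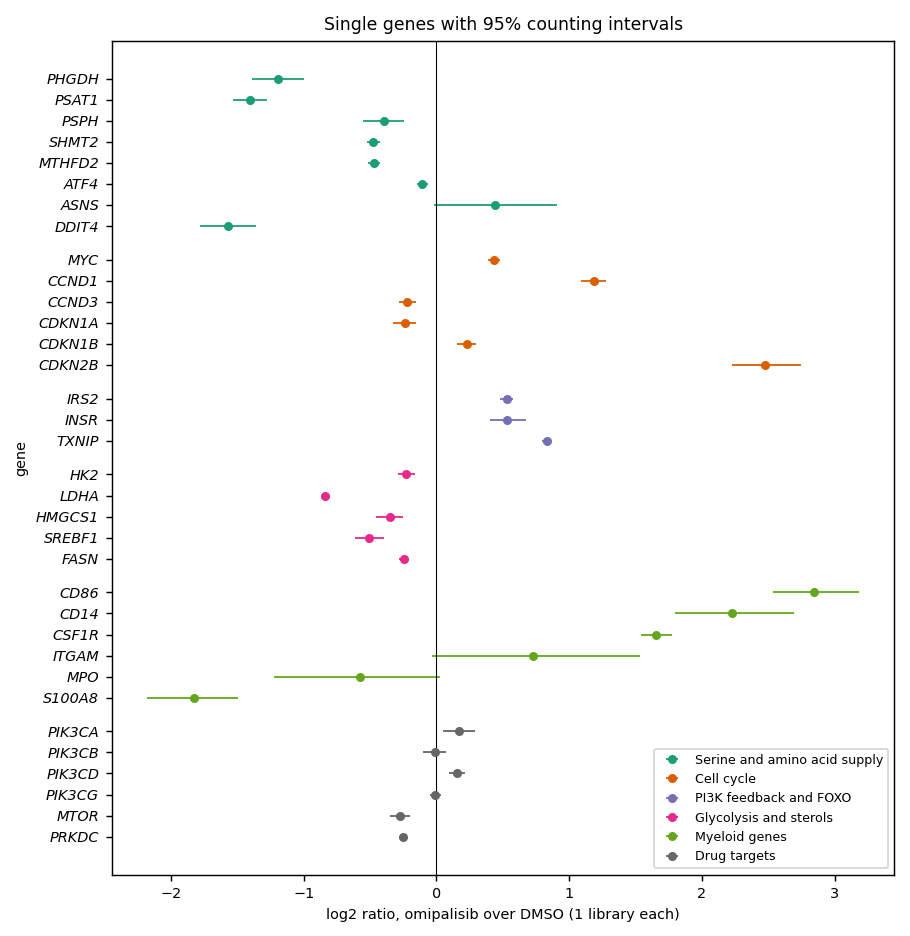
The plot shows the log2 ratio of single genes, omipalisib over DMSO with 1 library each, grouped by function, with points for the ratio and bars for the 95% counting interval. PSAT1 at −1.40 and DDIT4 at −1.57 lie far left of 0, CD86 at 2.85 and CDKN2B at 2.48 far right, and the 6 drug target genes lie between −0.27 and 0.17.

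Genes of serine synthesis were lower. Of the 12 measured genes of serine and one-carbon metabolism, 9 were lower, 1 was higher and 2 had intervals that included 0, and the median log2 ratio was −0.43 (interval over members −1.05 to −0.05), below all 10000 expression-matched random lists. PHGDH, which catalyses the committed step of serine synthesis from glycolysis, had 756 and 293 counts, a log2 ratio of −1.19. PSPH, the last enzyme of that route, had −0.40 (−0.55 to −0.24). The mitochondrial folate enzymes SHMT2 and MTHFD2 had −0.48 and −0.47, ALDH1L2 had −1.05, and MTHFD2L was the higher member at 0.50. ATF4 targets, the amino acid response genes, were lower in 23 of 28 with none higher, with a median of −0.38 (−0.59 to −0.21), also below all random lists. Examples were STC2, DDIT4 and JDP2 (−0.99). ATF4 itself had a log2 ratio of −0.11 (−0.15 to −0.07). ASNS, the asparagine synthetase, had only 74 and 89 counts, with a log2 ratio of 0.44 (−0.02 to 0.91), and its count is uncertain because it overlaps another annotated gene on its strand. Of the 20 cytosolic tRNA synthetases, 19 were lower, among them YARS1 (−0.74), GARS1 (−0.70) and MARS1 (−0.66), and QARS1 was higher at 0.10. Their median was −0.35 at percentile 0.01. The 12 genes of glutamine metabolism and transport, 8 lower and 2 higher, had a median of −0.14 at percentile 22.4, inside the random range. The glutamine transporter SLC1A5 had −0.55 and SLC38A2 had 0.24.

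Genes of cholesterol and of purine and pyrimidine synthesis were lower too. Of 24 genes of cholesterol synthesis and uptake, 20 were lower and none was higher, with a median of −0.34 at percentile 0.01. ACAT2 had a log2 ratio of −1.06 (−1.23 to −0.90), IDI1 −0.71, INSIG1 −0.68 and HMGCS1 −0.35. Of the sterol-regulatory transcription factor genes, SREBF2, in the cholesterol list, had −0.068 (−0.125 to −0.011). SREBF1, in the fatty acid list, had −0.51. Of 13 genes of fatty acid synthesis, 11 were lower and 1 was higher, with a median of −0.25 at percentile 3.08, inside the random range, but at 2.35 against unmatched random lists and 1.29 against lists matched on length too, both outside it. The stearoyl-CoA desaturase SCD had −0.98 (−1.03 to −0.93), FADS1 −0.62, FASN −0.25, and LPIN1 was higher at 0.22. FADS2 had −1.10 and overlaps FEN1 on the same strand. Of 23 glycolysis genes, 13 were lower and 4 higher, with a median of −0.25 at percentile 1.07, or 2.90, inside the random range, once a trend with gene length was removed. Lactate dehydrogenase LDHA had 22234 and 11025 counts, a log2 ratio of −0.84 (−0.87 to −0.81). The glucose transporter SLC2A1 had −0.68 and HK2 −0.23, and the transporter SLC2A3 was higher at 0.76. The 7 measured genes of the pentose phosphate pathway, 3 lower and 1 higher, had a median of −0.11 at percentile 42.9, with TKT at −0.11 and PGLS at 0.17. Purine and pyrimidine synthesis genes were lower in 16 of 19, with none higher and a median of −0.30 at percentile 0.23, among them RRM1 (−0.79), PAICS (−0.58) and PRPS1 (−0.54).

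Nuclear genes of the mitochondrial ribosome and respiratory chain were lower as groups, while the messages made in the mitochondrion lay inside the random range. The mitochondrial ribosome list was lower in 35 of 49 and higher in 4, with a median of −0.26, below all random lists, and MRPS7 had −0.67 (−0.75 to −0.60). The nuclear-encoded respiratory chain was lower in 38 of 50 and higher in 2, with a median of −0.23 at percentile 0.05. NDUFA1 had −0.97 (−1.11 to −0.84) and CYCS, cytochrome c, −0.55. TCA cycle genes were lower in 17 of 22 with none higher, with a median of −0.24 at percentile 0.93, including IDH2 (−0.50), DLD (−0.39) and MDH2 (−0.38). The mitochondrial biogenesis regulators were lower in 16 of 23 and higher in 2, with a median of −0.23 at percentile 1.61. TFAM, the mitochondrial DNA packaging factor, had −0.38 (−0.44 to −0.31), TOMM40 −0.62, HSPE1 −0.55 and POLG2 0.40. The 13 mitochondrially encoded mRNAs had a median of −0.07 at percentile 63.8, with 10 lower and 1 higher. MT-CO1 had 0.10 (0.10 to 0.11), MT-CYB −0.18 and MT-ND6 −0.88 (−0.91 to −0.85). With random lists matched on gene length as well, the TCA cycle and biogenesis lists lay inside the random range, at percentiles 3.58 and 4.05, and the biogenesis list also did so without a minimum count (4.06) and with the length trend removed (3.33).

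G1/S and G2/M genes were lower, while the D cyclins and CDK inhibitors went both ways. All 38 G1/S genes were lower, with a median of −0.70 (−0.75 to −0.65), below all random lists. CLSPN, a DNA replication checkpoint mediator, had a log2 ratio of −1.08 (−1.17 to −0.99), CDC6 −0.99 and MCM10 −0.93. Of 36 G2/M genes, 34 were lower and none was higher, with a median of −0.63, also below all random lists, among them CDC20 at −1.03 (−1.10 to −0.96), MYBL2 (−0.98) and BUB1 (−0.97). Of the 10 measured D cyclins and CDK inhibitors, 4 were higher and 5 lower. Their median was −0.22 at percentile 6.04, while their mean was 0.32, opposite in sign. CCND1, cyclin D1, had 1300 and 2617 counts, a log2 ratio of 1.18 (1.09 to 1.28), and CDKN1B, p27, had 0.23 (0.16 to 0.30). CCND3 had −0.22 (−0.29 to −0.15), CDK4 −0.35, CDKN2C −0.34, CDK6 −0.22 and CDKN1A, p21, −0.24 (−0.33 to −0.16). CCND2 had 0 and 1 counts, too few for a ratio.

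Relative to the rest of the library, messages for the machinery that builds ribosomes and for the ribosomal proteins differed in opposite directions. Of 37 genes of ribosome biogenesis and MYC targets, 30 were lower and 1 was higher, with a median of −0.33, below all random lists. ODC1, the polyamine synthesis enzyme, had −0.92 (−0.99 to −0.85), MRTO4 −0.57 and NPM1 −0.58. NPM1 has many processed pseudogenes, so its count is uncertain. The higher member was MYC itself, with 8106 and 9694 counts and a log2 ratio of 0.43 (0.39 to 0.48). Of 78 cytosolic ribosomal protein genes, 62 were higher and 11 lower, with a median of 0.24 (0.16 to 0.28), above all random lists. RPL39 had 0.57, RPL3 0.47 and RPL12 0.45, while RPS26 was lower at −0.45. These genes share sequence with pseudogenes, so their levels are uncertain. Translation factors with 5′ TOP messages, whose translation depends on mTOR, were higher in 10 of 13 and lower in 2, with a median of 0.21 at percentile 99.57. TPT1 had 0.45, RACK1 0.38 and PABPC1 0.32, and EEF1D was lower at −0.11. Against random lists without matching, the TOP list lay at percentile 92.4.

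FOXO targets were higher. FOXO factors are held out of the nucleus by AKT, downstream of PI3K. Of 32 measured targets, 24 were higher and 4 lower, with a median of 0.40 (0.23 to 0.69), above all random lists. FBXO32, a ubiquitin ligase of muscle atrophy, had 35 and 133 counts, a log2 ratio of 2.09 (1.55 to 2.68), KLHL24 had 1.56 (1.37 to 1.75) and BCL6 1.09 (0.93 to 1.24). The receptor pathway genes INSR and IRS2 had 0.54 (0.40 to 0.67) and 0.53 (0.48 to 0.58), and TXNIP, a regulator of glucose uptake, had 12582 and 19817 counts, a log2 ratio of 0.83 (0.80 to 0.86). CAT, catalase, was lower at −0.57. MAPK output genes were higher in 19 of 24 and lower in 1, with a median of 0.37 (0.12 to 0.98), above all random lists, and 6 of them were at least 2-fold higher. EGR1 had 1227 and 3293 counts, a log2 ratio of 1.60, DUSP4 1.65 (1.42 to 1.88) and EGR3, with 15 and 71 counts, 2.38 (1.60 to 3.33). The phosphatase gene DUSP6 had 0.98 and SPRY4 0.78. FOS was the lower member, at −0.40 (−0.53 to −0.28).

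The genes for the drug's targets had log2 ratios between −0.27 and 0.17. PIK3CA and PIK3CD were higher, MTOR and PRKDC were lower, and PIK3CB and PIK3CG had intervals that included 0. PIK3CA had a log2 ratio of 0.17 (0.05 to 0.29), PIK3CD 0.15 (0.09 to 0.21), PIK3CB −0.01 (−0.10 to 0.07) and PIK3CG −0.01 (−0.05 to 0.03). MTOR had −0.27 (−0.35 to −0.20) and PRKDC, the DNA-dependent protein kinase, −0.25 (−0.28 to −0.22). The 34 measured PI3K-AKT-mTOR components, 11 higher and 15 lower, had a median of −0.05 at percentile 67.3. DEPTOR, an mTOR inhibitor, had 1.48 (0.91 to 2.11), the regulatory subunit PIK3R3 −1.09 (−1.34 to −0.85) and EIF4EBP1 −0.45. Lysosome and autophagy genes (TFEB targets) were split, 15 higher and 14 lower of 39, with a median of 0.04 at percentile 93.6, or 99.16 with the length trend removed. GABARAPL1 had 0.87, SQSTM1 0.74, TPP1 0.46 and GLA −0.38. The 14 BCL2 family genes were also split, 5 higher and 5 lower, with a median of 0.01 at percentile 70.4. The proapoptotic BMF had 517 and 1518 counts, a log2 ratio of 1.73 (1.58 to 1.87), and the antiapoptotic BCL2A1 had 1.64 (1.30 to 1.99). BBC3 had 0.57, BCL2 0.21, MCL1 0.12 and PMAIP1 −0.50. Of 23 p53 targets, 8 were higher and 10 lower, with a median of 0.01 at percentile 69.1, with GDF15 at 0.98, TP53INP1 at 0.77 and AEN at −0.58.

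Chaperone and interferon genes were lower. Of 21 endoplasmic reticulum and heat stress genes, 17 were lower and 4 higher, with a median of −0.59 (−0.74 to −0.34), below all random lists. CALR, calreticulin, had 34968 and 15329 counts, a log2 ratio of −1.02 (−1.04 to −0.99). HSPH1 had −0.84 and PDIA4 −0.78, and HERPUD1 was higher at 0.48. Of 30 interferon-stimulated genes, 27 were lower and 2 higher, with a median of −0.45 (−0.67 to −0.31), below all random lists. IFIT1 had 7543 and 3488 counts, a log2 ratio of −0.94, OASL −0.94, and STAT2 was higher at 0.14. CXCL10 had 38 and 3 counts, a log2 ratio of −3.29 (−5.83 to −1.83). Antigen presentation genes, 7 higher and 5 lower of 14, had a median of 0.04 at percentile 87.8, with HLA-E at 0.47 and PSMB8 at −0.29. HLA genes share sequence with one another and are uncertain. Inflammatory NF-kB targets, 9 higher and 5 lower of 22, had a median of 0.11 at percentile 89.1, with IER3 at 1.61, CXCL3 at 1.42, CCL5 at 0.80 and CD83 at −0.54. HIF targets, 10 lower and 5 higher of 19, had a median of −0.23 at percentile 1.45, with DDIT4, LDHA and SLC2A1 lowest and MXI1 at 1.03. They lay inside the random range, at percentile 8.11, when the DMSO library was thinned to the depth of the other. The same held, at percentile 7.06, when only genes with at least 200 counts were kept. NRF2 targets, 12 lower and 2 higher of 17, had a median of −0.24 at percentile 1.49, with HMOX1 at −1.19, GCLM at −0.78, NQO1 at −0.69 and ABCC1 at 0.18, and lay at percentile 3.45 when only genes with at least 200 counts were kept.

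Myeloid genes moved apart. Of 26 measured monocyte and macrophage genes, 14 were higher and 5 lower, with a median of 0.25 (0.02 to 0.67) at percentile 99.84. CSF1R, the receptor for macrophage colony-stimulating factor, had 834 and 2332 counts, a log2 ratio of 1.66 (1.54 to 1.77), next to CD86 and CD14, while S100A8 went the other way. ITGAM, the CD11b gene, had 25 and 37 counts, a log2 ratio of 0.73 (−0.03 to 1.53). The 11 primary granule genes, 5 higher and 5 lower, had a median of −0.31 at percentile 1.63. CTSG, cathepsin G, had 3988 and 1769 counts (log2 interval −1.08 to −0.92), PRTN3 had −0.96 (−1.07 to −0.85) and RNASE2 −0.60, whereas SERPINB1 had 4854 and 8325 counts, a log2 ratio of 0.95. MPO had 61 and 36 counts, a log2 ratio of −0.58 (−1.22 to 0.03). This list lay at percentile 34.6 when only genes with at least 200 counts were kept. The 10 neutrophil maturation genes, 5 higher and 2 lower, had a median of 0.08 at percentile 66.3, with the receptor gene CSF3R at 1.10 (1.01 to 1.19), CEACAM1 at 2.09 from 6 and 24 counts and FPR1 at −0.89. NCF1 had 0.72 and is uncertain, since near-identical pseudogenes share its sequence. Stem cell and HOX genes, 11 higher and 3 lower of 26, had a median of 0.14 at percentile 95.04, or 97.85 with the length trend removed, with IL3RA at 1.02, LMO2 at 0.71, CD44 at 0.46 and ERG at −0.40.

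Some of the markers chosen for other cell types were expressed in both libraries. Of 26 erythroid and megakaryocyte markers, 5 were measured, with a median of −0.69 (range −1.35 to 1.03) at percentile 0.33, and the list lay at percentile 60.9 without a minimum count, with a median of 0.17. TFRC, which dividing cells use for iron uptake, and EPOR, with 238 and 245 counts, were the abundant members, and the rest had few counts, such as PPBP with 47 and 16 (log2 ratio −1.35) and ITGA2B with 23 and 42 (1.03). Of 25 lymphoid markers, 7 were measured, 3 higher and 2 lower, with a median of 0.08 at percentile 54.5, or 1.22 without a minimum count. CD4, which monocytic cells also express, had 7658 and 7226 counts, a log2 ratio of 0.09, EBF1 had −1.19, and GNLY (1.84) and CD79A (1.68) had fewer than 20 counts in each library. Of 25 stromal and epithelial markers, 11 were measured, 4 higher and 2 lower, with a median of 0.17 at percentile 85.5. At least 1 CPM was reached by 8 of them in DMSO and 9 in omipalisib. VIM, which leukocytes also express, stood at 969.5 and 940.9 CPM, FN1 at 106 and 115 CPM (log2 ratio 0.11, or −0.015 with the length trend removed) and COL1A2 at 96.7 and 68.0 CPM (−0.51). PECAM1, also a leukocyte gene, had a log2 ratio of 0.93 and COL6A2 0.57.

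Of 13 measured replication-dependent histone genes, 8 were higher and none was lower, with a median of 0.74 (−0.25 to 1.27) at percentile 99.97, and the list lay at percentile 87.2 without a minimum count. H2AC6 had 570 and 1297 counts, a log2 ratio of 1.36 (1.22 to 1.51), H4C8 1.34 and H2BC21 1.27. The main transcripts of these genes lack a poly(A) tail and the genes resemble one another. The way RNA was selected for the libraries is not given in the sources used here, so the histone counts are uncertain, as are those of noncoding RNAs without such a tail. Long noncoding RNAs and snoRNA hosts were higher in 10 of 13 and lower in 2, with a median of 0.33 (−0.08 to 0.36) at percentile 99.97. NEAT1 had 0.71 (0.67 to 0.76), NORAD 0.47 and GAS5 0.35, and SNHG12 was lower at −0.48.

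**Figure D2:**
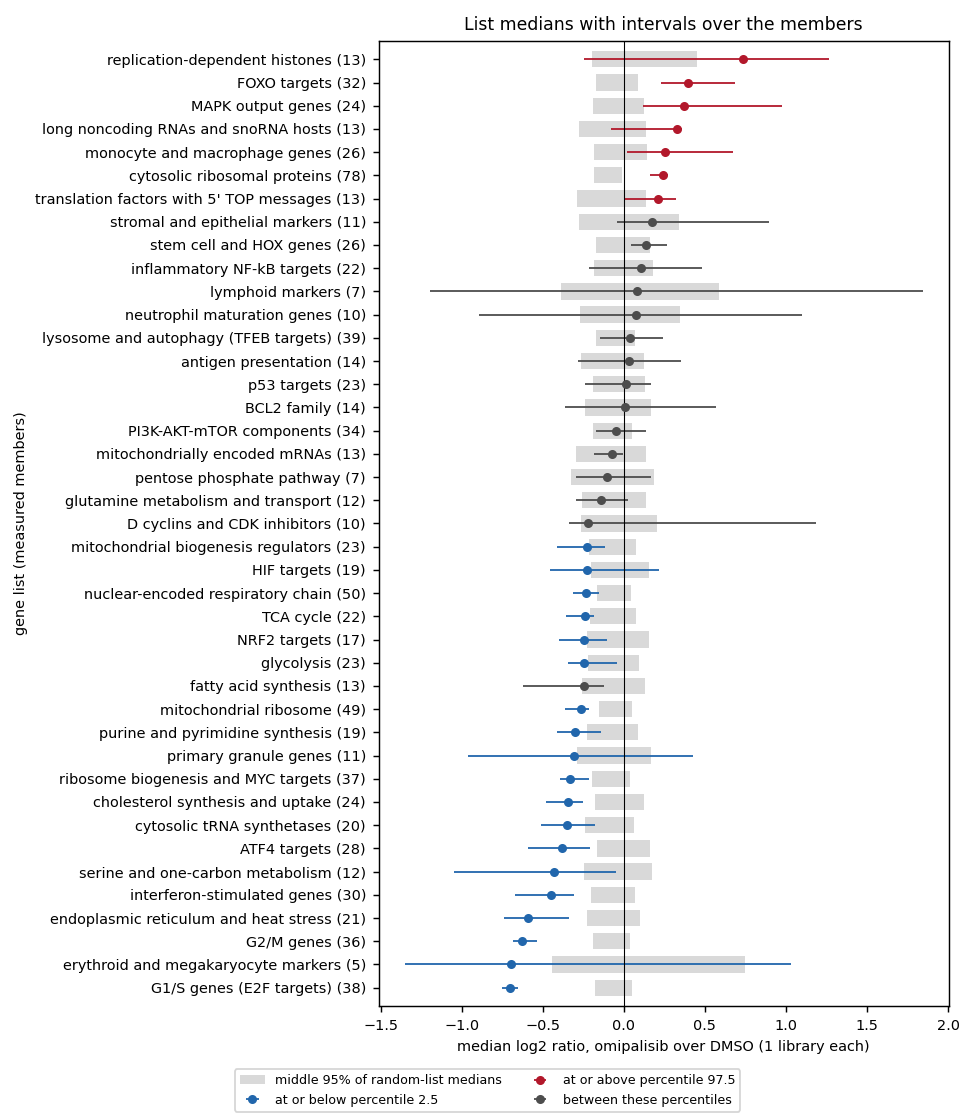
The plot shows the median log2 ratio of each of the 41 gene lists, omipalisib over DMSO with 1 library each, with bars for the 95% interval of the median over the list's members (the range for the 5 erythroid and megakaryocyte markers) and grey bands for the middle 95% of medians of 10000 expression-matched random lists. G1/S genes at −0.70 and G2/M genes at −0.63 lie left of their bands, and FOXO targets at 0.40 and MAPK output genes at 0.37 lie right of theirs.

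Over the 41 lists, 19 lay at or below percentile 2.5 of their random lists, 7 at or above 97.5 and 15 between. These percentiles describe the 2 libraries and are not a test of the treatment.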

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

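The alternative that subtracts the length trend was the only one chosen after seeing the data. The count of genes at least 2-fold higher or lower was within 1.5 times the original under the other scalings, 5 added counts, thinning, no minimum count and length trend removal, with 69.9% to 80.5% of counted genes higher against 75.7%. Stricter or looser definitions changed it by construction, since they admit fewer or more genes: 193 higher and 37 lower with at least 200 counts, 1501 and 746 at a ratio of 1.5, 63 and 25 at a ratio of 4, 152 and 31 with the whole interval past 2, and 366 and 124 among protein-coding genes alone. The sign of the median changed under at least 1 of the 11 alternatives for 7 lists. Of these, 6 lay between the percentiles as reported: BCL2 family, p53 targets and antigen presentation turned negative with median-of-ratios scaling, PI3K-AKT-mTOR components turned positive with both totals, and lymphoid markers and D cyclins and CDK inhibitors turned without a minimum count. The remaining list, erythroid and megakaryocyte markers, reversed to 0.174 without a minimum count, which admits more genes. Medians moved beyond their intervals for cytosolic ribosomal proteins, to 0.29 with total counts and 0.30 with totals that leave out mitochondrial and the most abundant genes, and for the long noncoding RNA list, to 0.38 and 0.39. The latter totals also moved the mitochondrial ribosome to −0.21 and G1/S genes to −0.64. All of these moves are the shift of the scaling itself. Of the 41 lists, 28 kept their side of the percentiles throughout and 13 changed it at least once, none of them through scaling. Removing the length trend took glycolysis to percentile 2.90, mitochondrial biogenesis regulators to 3.33 and primary granule genes to 4.98, between the limits, and fatty acid synthesis to 1.04, below them. It took lysosome and autophagy genes to 99.16 and stem cell and HOX genes to 97.85, above them, and the cause was not tested. Without a minimum count, lymphoid markers lay at 1.22. Of the 196 named genes, the called direction of 1 reversed: FN1 went from 0.11 to −0.015 after the length trend was removed, and the cause was not tested. No paired analysis was possible because each group has 1 library. Depth limits genes such as MPO and ITGAM, whose intervals include 0, and differences between cultures could not be estimated.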

Other observations

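The gene family screen, the test for admixed monocytes and the tests for shared fragments among ABCA genes were chosen after the results were seen, as were the families and genes singled out here; the other tests had their predictions written before their results.

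A screen covered 206 protein-coding gene families, defined by a shared symbol stem with at least 8 measured members. Members of the fixed lists were not left out, so families such as MCM, MRPL and RPL share many genes with those lists. If family members varied independently, 10.3 families would lie outside the 2.5 and 97.5 percentiles of expression-matched random lists, and 22 lay low and 24 high. When random lists were matched on gene length too, 17 of the low and 18 of the high families kept their side. Members of a family can vary together, also between cultures for reasons other than the drug. The counts are therefore not a test of the treatment. Among the low families, 13 of 14 PSMD genes, which encode the proteasome's regulatory particle, were lower, with a median log2 ratio of −0.47 (PSMD14 −0.75), as were 7 of 8 genes of the CCT stem, mostly chaperonin subunits, with a median of −0.53 (CCT2 −0.59), and 10 of 13 HSPA chaperones, with a median of −0.53. HSPA8 alone had 143259 and 76171 counts, a log2 ratio of −0.74. Of 22 NUP nucleoporin genes, 19 were lower and 1 was higher, with a median of −0.37. Some members, such as HSPA8, were also in the fixed stress list. Of other chaperone and ubiquitin families, DNAJB (percentile 36.8) and UBE (31.9) lay inside the random range. The ubiquitin ligase families RNF and FBXL lay just past the high limit, at percentiles 97.51 and 97.77. RNF was split, 19 higher and 18 lower of 63, with a median of 0.056. FBXL had 6 higher and 2 lower of 14, with a median of 0.22 (−0.20 to 0.41). FBXO (66.05) and TRIM (66.21), which also hold ubiquitin ligase genes, lay inside the random range.

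Among the families that were higher, ABCA genes were higher in 8 of 8, with a median of 1.05. TNFRSF receptor genes were higher in 7 of 11 with none lower and a median of 0.46 (TNFRSF1B 0.71), SEMA genes in 11 of 16 with none lower and a median of 0.41, collagen (COL) genes in 9 of 13 with 1 lower and a median of 0.54, and KLF transcription factor genes in 9 of 13 with 2 lower and a median of 0.41. Abundant single genes outside the lists were also higher: SPTLC2, a subunit of the enzyme that starts sphingolipid synthesis, had 9458 and 18014 counts, a log2 ratio of 1.10 (1.07 to 1.14), and IGFBP5 had 5834 and 13898 counts, a log2 ratio of 1.43 (1.38 to 1.47).

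Long genes were higher relative to short genes. Over 10238 protein-coding genes with at least 200 counts, the median log2 ratio went from −0.17 in the tenth with the shortest exon length to 0.08 in the longest, a difference of 0.245 (Spearman's rho 0.206 across genes, which are not independent). Short genes of the fixed lists do not account for it, since the difference was 0.243 without list members, and GC content does not: the fifth of genes with the longest exons lay 0.201 above the fifth with the shortest, and within groups of like GC content this difference was 0.208 on average. A length-dependent step of library preparation or counting stays open: inside lists, longer members lay 0.043 above shorter ones (bootstrap 0.014 to 0.102), which is too wide to decide. The treatment may also differ in its effect on long and short genes, and with 1 library per group that cannot be told apart from a preparation effect.

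Monocyte surface genes were higher while S100A8 (−1.82) and S100A9 (−1.31) were lower. The length trend was excluded as the whole source, since CD86, CD14 and CSF1R kept a median of 2.203 after its removal. Admixed monocytes in the omipalisib library stay open: leaving out S100A8 and S100A9, which define the pattern, the abundant monocyte transcripts went both ways, with LYZ at −0.39, VCAN at 0.50 and FCN1 at 0.74 and a median of 0.499. FCN1 had 10 and 15 counts and S100A12 9 and 3, beside 53 and 221 for CD14, but no monocyte profile was used here to set the levels that admixture would need. An effect of the drug and a difference between these 2 cultures unrelated to it also stay open and were not tested.

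ABCA5 (1.69), ABCA6 (1.79), ABCA9 (2.62) and ABCA10 (1.34), which lie together on chromosome 17 between 68974488 and 69327244 (GRCh38), were higher together. A gained chromosomal segment that covered the neighbours would raise them. The 40 nearest measured genes, from position 64498254 to 74873031, had a median log2 ratio of 0.153 (−0.126 to 0.268), far under the cluster's. This argues against a gain of that whole stretch. A gain of the cluster with few neighbours would leave the median little changed, so it stays open. Fragments of 1 gene counted for another would give these related genes like ratios. Fragments with several alignments are left out by default, and those in the same-strand overlap of ABCA5 and ABCA10 count for neither. If the default was used, only fragments placed on the wrong member alone could make the ratios alike. ABCA9 lay above the intervals of the other members by 0.438, which argues against this as the source of its ratio. The intervals of ABCA5, ABCA6 and ABCA10 overlapped (−0.091), which does not show that their ratios are the same. For these genes the explanation stays open. No biological explanation was tested.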
